A study of Mus musculus with 18 samples.

How the data were processed

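RNA from 4 cultured mouse bone marrow progenitor populations was measured on 18 Illumina bead arrays. The populations were eosinophil progenitors (EoP), basophil progenitors (BaP), mast cell progenitors (MCP) and megakaryocyte/erythrocyte progenitors (MEP), from C57BL/6J mice aged 12 weeks, each cultured for 48 hours with or without 50 ng/ml IL-33. Each of the 8 groups held 2 arrays, except the MEP groups, which held 3. EoP, BaP and MCP cultures contained 1 ng/ml IL-3, whereas MEP cultures contained 2 ng/ml IL-3 with SCF, IL-11, thrombopoietin and 0.5 U/ml erythropoietin. MCP were taken from granulocyte/macrophage progenitors after 4 days of culture. Replicate labels did not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

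The deposited table holds the bead signal intensity of 45281 probes on a linear scale, not normalized between arrays, and a detection p-value per probe and array, per the file headers. The submitters' processing notes name BeadStudio, with no version. A second table from the authors, the series matrix, also holds linear signal intensity. Its probe ranks within each array equalled those of the first table (rank correlation of 1), and its values showed 2 shared distributions, one over 12 arrays (EoP, BaP and MCP) and one over the 6 MEP arrays. Quantile normalization in 2 separate sets was read from these values, since no source used here states it. No background subtraction is stated in the sources used here, and no signal was at or below 0.

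Signals were background-corrected by the normal-exponential model with negative-control parameters inferred from the detection p-values (neqc in limma 3.58.1, R 4.3.3), with an offset of 16, then quantile-normalized over the 18 arrays and expressed as log2. Detection at p under 0.05 on at least 2 arrays was required, which kept 24278 probes. The platform annotation gave 1 gene symbol to 34885 probes, several to 18 and none to 10378, and 34807 symbols were looked up again through their Entrez identifier, which changed 0 of them (names only, GRCm38.p6). Probes with several symbols or none entered no gene comparison. Where a gene had several kept probes, the probe with the highest mean log2 signal stood for it, which left 12447 genes. Among 51 called named genes with other kept probes, all other probes had a change of the same sign for 43. For 23 at least 1 further probe stayed level, with a change under 0.5 log2 units in either direction. Il1rl1, which encodes the IL-33 receptor chain ST2, had no named probe here and was not analysed here.

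One limma model with 8 group means was fitted to all arrays, with a shared moderated variance per gene (10 residual and 3.78 prior degrees of freedom) and Benjamini-Hochberg adjustment over the genes in each comparison. Genes were called at an adjusted p under 0.05. The comparisons were IL-33 against control in each population, the difference of the IL-33 effect between each pair of populations, and genes higher in one population's controls than in each of the other populations' controls. Of 26 gene lists fixed before the data were examined, 25 were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The last list, of sex-linked genes, served as a sample check. Text counts of list members adjusted over the list alone use only that list's genes.

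Genes were named by a rule written before the data were examined. It took the 8 largest rises and the 8 largest falls among called genes whose arrays did not overlap, the 2 largest called members of each list with at least 3 called members, and a fixed set of cytokine and receptor genes. For differences it took the 3 largest per pair, and for controls the 5 genes that stood furthest above the other populations plus called members of the population's marker list. Other genes are named with a statement that they were chosen after their values were seen. A probe not detected on any array of a group has only a bound there. The change is then given as at least N-fold, from the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal. No fold is given where both groups were below detection.

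Between 16246 and 19005 probes were detected per array (35.9% to 42.0%), and array median signals ran from 42.6 to 64.2. The number of arrays limits the precision. In simulated arrays with known changes and one spread for all populations, run on 12447 genes, 94 of 100 genes changed by 2 log2 units were recovered for IL-33 in EoP, 94 in BaP, 93 in MCP and 99 in MEP. For changes of 1 log2 unit, 39, 45, 37 and 68 of 100 were recovered. With that same single spread, differences of 2 log2 units between populations were recovered in 75.3% (BaP and MCP) to 87.9% (MCP and MEP) of simulated genes. The changed genes of these simulations had mean signals well above detection, so recovery of genes near detection was not measured. When each population kept its own spread, 86 of 247 simulated calls in MEP were false (34.8%), against 0 in EoP, 0 in BaP and 2 in MCP. Differences between populations were not simulated with these separate spreads, so false calls among differences with MEP were not measured there. The residual SD was 0.405 in MEP, 0.251 in EoP, 0.162 in BaP and 0.255 in MCP, so the shared variance understated the MEP spread and overstated the BaP spread. Alternatives covered background correction, offset, scaling, the authors' series matrix values, detection filters, single probes, variance models, arrays entering the fit, replicate blocks and the removal of each array. Slide was not run as a block because no slide is given in the sources used here.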

Results

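Gene expression was measured in eosinophil, basophil, mast cell and megakaryocyte/erythrocyte progenitors (EoP, BaP, MCP and MEP) after 48 hours of culture with or without 50 ng/ml IL-33, an IL-1 family cytokine. The design asked which genes IL-33 changed in each population and how the responses differed. There were 2 arrays per group for EoP, BaP and MCP and 3 per group for MEP. Arrays of the same group correlated across genes at r of 0.990 or more for EoP, BaP and MCP, and at 0.965 to 0.992 for MEP, although genes are not independent replicates. Correlation of MEP control arrays with the other controls was lower, at 0.696 to 0.753. MEP differed from the other populations in medium as well, and the authors' normalized values placed their arrays in a separate set. Population, medium and array set therefore cannot be told apart in any comparison with MEP. Xist, the X-inactivation transcript, was also lower in every MEP array than in every other array. A difference in the source of the mice therefore cannot be told apart from these either. MCP alone came from granulocyte/macrophage progenitors cultured for 4 days, so population and that origin cannot be told apart in comparisons with MCP.

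Each population's controls were highest for markers of their lineage, but only for part of the basophil and megakaryocyte lists. EoP controls were also highest for neutrophil genes. In EoP controls 8 of 9 measured eosinophil markers were higher than in each of the other populations, among them Epx (eosinophil peroxidase, 13.07 ± 0.15 log2 signal, SD, n = 2) and Prg3 (a granule protein, 13.84 ± 0.08). Genes far above the other populations in EoP were Ltf, Cebpe, S100a9, Prtn3 and Camp. Of these Ltf, S100a9, Prtn3 and Camp encode proteins of neutrophils and Cebpe a granulocyte transcription factor. S100a9 was at least 215-fold higher in EoP than in any other control group. BaP controls had 6 of 12 basophil markers at the highest level, including Itga2 (integrin alpha 2, CD49b), at 11.68 ± 0.40 against 6.52 ± 0.20 in EoP, and Mcpt8 (a basophil protease), at 12.81 against 11.68 in EoP. MCP controls were highest for 12 of 15 mast cell markers, including the proteases Tpsb2, Cma2 and Mcpt4, which were at least 354-fold, 149-fold and 102-fold above the other controls. In MEP controls 22 of 25 erythroid genes were highest, including Slc4a1 (the band 3 anion exchanger), at least 541-fold, and Alas2 (the first enzyme of erythroid heme synthesis). Only 2 of 17 megakaryocyte and platelet genes, Treml1 and Tubb1, were highest in MEP, against 4 in MCP. In total 593 genes were highest in EoP, 1418 in BaP, 845 in MCP and 2817 in MEP. With median scaling these numbers were 2245 for BaP and 1856 for MEP, so the sizes of those sets depended on the scaling.

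In EoP, IL-33 raised NF-kB genes and some chemokine and neutrophil genes and lowered basophil markers. Of 9 eosinophil markers 8 were not called, some of them near the top of the scale, where a rise could hardly be measured. Il1b, which encodes interleukin-1 beta, rose by 7.63 ± 0.42 log2 units (SE, n = 2 and 2, limma adjusted p = 5.98e-08) and was detected on 1 of 2 control arrays. Akr1c18, a progesterone-metabolizing reductase, fell by 5.01 ± 0.31 log2 units (adjusted p = 1.83e-07). Of 12447 genes, 415 rose and 214 fell. Other large rises were Myl4 (a myosin light chain, 5.30), Mras (a Ras-family GTPase, 4.79), Mmp2 (a matrix metalloproteinase, 4.09), Slc6a12 (a betaine transporter, 4.05), Pilra (an inhibitory receptor, 3.97), Ppfibp2 (3.64) and Stfa2 (a cysteine protease inhibitor, 3.59). Slc6a12 and Stfa2 were each detected on 1 of 2 control arrays, and 1 of 2 further Ppfibp2 probes did not move with the chosen one. Falls included Trgv4 (a T cell receptor gamma segment, -4.56), Hal (histidine ammonia-lyase, -4.38), Muc20 (-3.06), Grm6 (-2.83), Cd244a (-2.62), Mfsd2a (a lipid transporter, -2.58) and Cdh1 (E-cadherin, -2.56). Trgv4, Hal, Muc20 and Cd244a were detected on 1 of 2 arrays with IL-33, and Cd244a was not called by a fit to the EoP arrays alone (adjusted p = 0.121).

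The list of NF-kB targets and feedback genes shifted upward in EoP, with 14 of 25 members rising, 0 falling and 11 not called (camera adjusted p = 4.69e-20, and 14 rose when adjusted over the list alone). Relb, an NF-kB subunit, rose at least 8.52-fold, and Nfkbiz, an inhibitor-family nuclear regulator, rose by 3.13 log2 units. Among chemokines 5 of 17 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 6.65e-04). Cxcl16 rose at least 6.08-fold and Ccl24, an eosinophil-attracting chemokine, by 2.37, with detection on 1 of 2 control arrays. A further Cxcl16 probe stayed level. Basophil markers fell in 9 of 12 cases and 3 were not called (9 adjusted over the list alone, camera adjusted p = 4.83e-13). The list's median change was -1.23. Mcpt8 fell by 2.26 ± 0.13 and Itga2 fell at least 2.64-fold. Fcer1a, the IgE receptor alpha chain that basophils and mast cells share, fell by 1.31, a call that was lost without any 1 of the 4 EoP arrays (adjusted p from 0.0660 to 0.193). Neutrophil markers rose in 6 of 16 cases and fell in 0 (8 and 0 adjusted over the list alone, camera adjusted p = 1.36e-08), with Ngp at 2.29 and Fcnb at 2.05. Of the eosinophil markers 8 of 9 were not called and 1 fell. In EoP controls Ear6, Ear3, Cebpe and Prg3 stood at 14.28, 14.18, 14.00 and 13.84, and the highest gene at 14.41. These markers had little room to rise, whereas Alox15 (7.22) and Il5ra (6.41) had room.

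Cytokine genes in EoP rose in 4 of 18 cases and fell in 2 (8 and 3 adjusted over the list alone). Their camera adjusted p was 0.00178, and the adjusted p was 0.0711 with an estimated correlation. Il1a rose at least 3.29-fold and Csf2, which encodes GM-CSF, at least 1.81-fold. Il4 was high in both groups (12.81 and 12.80 log2) and was not called, Il5 and Il9 were below detection in both, and Il6 and Il13 were not called at -0.70 and 0.79, although Il13 passed with the authors' series matrix values and with MEP arrays normalized apart (adjusted p = 0.0382 and 0.0444). Antigen presentation genes rose in 3 of 12 cases (3 adjusted over the list alone, camera adjusted p = 0.00151), including the costimulatory ligand Cd80 (2.41) and Cd74, the invariant chain (1.87), and the list had an adjusted p of 0.0888 with an estimated correlation. The 1 further Cd80 probe and 1 of 2 further Cd74 probes stayed level. Interferon response genes rose in 4 of 19 (4 adjusted over the list alone, camera adjusted p = 0.00886), with Gbp3 at 2.00, detected on 1 of 2 control arrays, and Gbp2 at 1.75. Immediate early genes rose in 3 of 16 (4 adjusted over the list alone, camera adjusted p = 0.00208), with Egr2 at 1.32 and Dusp2 at 1.12. The adjusted p was 0.0888 and 0.0711 with an estimated correlation for these last lists. In the EoP arrays alone Gbp3, Cd74, Egr2 and Dusp2 were not called (adjusted p = 0.0759, 0.105, 0.240 and 0.0653). Gbp2, Cd74, Egr2 and Dusp2 were not called without EoP control replicate 2, with changes of 1.61, 1.31, 0.69 and 0.95. Without EoP IL-33 replicate 1, Gbp2, Egr2 and Dusp2 were not called, with changes of 1.69, 1.20 and 0.98. Egr2 was also lost without EoP IL-33 replicate 2 (change of 1.44). The interferon list was lost without EoP control replicate 2 or EoP IL-33 replicate 2 (list median 0.17 and 0.15). The unfolded protein response list shifted downward while limma called 0 of its 16 genes (5 at an unadjusted p under 0.05, camera adjusted p = 0.00466). Its adjusted p was 0.0888 with an estimated correlation and 0.0507 without EoP control replicate 2. Of monocyte markers, Cd14 (2.48) and Csf1r (1.47) rose, within a list that camera did not call. Csf1r lost its call without EoP control replicate 1 or EoP IL-33 replicate 2 (adjusted p = 0.0546 and 0.0530). A fit to the EoP arrays alone called 349 genes, and 307 of them were among the 629.

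In BaP, IL-33 raised NF-kB genes and some cytokine and chemokine genes and lowered eosinophil genes. Csf2 rose by 5.37 ± 0.17 log2 units (SE, n = 2 and 2, adjusted p = 6.59e-11). Il1a rose at least 139.5-fold and Il10 at least 155-fold, both from controls below detection. Tph1, the rate-limiting enzyme of serotonin synthesis in non-neuronal cells, rose by 8.66 ± 0.30, with detection on 1 of 2 control arrays. Ear6, an eosinophil-associated ribonuclease, fell at least 45.3-fold. In all, 527 genes rose and 302 fell. Further rises included Dgat2 (triglyceride synthesis, 6.13), Smpdl3b (5.78), Gstt4 (a glutathione transferase, at least 41.9-fold), Serpinb3a (a serpin, at least 40.3-fold, with the 1 further probe level) and Tpbg (at least 39.7-fold). Further falls included Ear3 (-4.92, detected on 1 of 2 arrays with IL-33), Nkg7 (a granule protein of cytotoxic cells, -4.23), Chil5 (a chitinase-like protein, -4.17), Hrh4 (the histamine H4 receptor, -4.02), Ifitm6 (-3.93), Sytl2 (-3.63) and Sncaip (at least 12.3-fold).

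Of 18 cytokine genes in BaP, 9 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 2.97e-17). Il13 rose by 1.96 ± 0.25 and Il9 at least 1.83-fold. Il4 (0.50), Il6 (0.65) and Il5, detected on 1 of 2 arrays with IL-33, were not called. Il4 was high in both groups (13.30 and 13.79 log2), where a large rise could hardly be measured. Il4 passed in a fit to the BaP arrays alone (adjusted p = 0.0158), Il5 without BaP IL-33 replicate 1 (5.02e-04) and Il6 without BaP control replicate 2 (0.0481). NF-kB genes rose in 15 of 25 cases (16 with 1 falling adjusted over the list alone, camera adjusted p = 7.58e-19). Tnfrsf9, a TNF receptor family member, rose by 4.59, from controls detected on 1 of 2 arrays, and Cd40 at least 6.98-fold. Of further probes, 1 of 2 for Tnfrsf9 and 1 of 3 for Cd40 stayed level. The neutrophil-attracting chemokines Cxcl1 (4.52) and Cxcl2 (3.98) were among 4 of 17 chemokines that rose (5 adjusted over the list alone, camera adjusted p = 9.40e-06). Cytokine receptors rose in 5 of 20 cases and fell in 2 (the counts adjusted over the list alone were also 5 and 2, camera adjusted p = 0.0155), with the decoy receptor Il1r2 at least 15.97-fold higher and Il2ra higher by 4.22. The STAT5 and SOCS list also shifted upward, with 2 of 12 rising both overall and adjusted over the list alone (camera adjusted p = 0.00268).

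Eosinophil markers fell in 6 of 9 cases in BaP and 3 were not called (6 adjusted over the list alone, camera adjusted p = 7.88e-08). The list's median change was -1.88, and -1.52 with genes below detection held at their bound. Basophil markers fell in 4 of 12 (4 falling and 1 rising adjusted over the list alone, camera adjusted p = 0.00592), with Itgb7 at -1.16 and Il18rap at -1.05, for which the 1 further probe stayed level. Both of these lost their call without any 1 of the 4 BaP arrays (adjusted p from 0.0740 to 0.186 and from 0.0525 to 0.149). Mast cell markers rose in 4 of 15 (7 adjusted over the list alone, camera adjusted p = 0.00106). Kit, the stem cell factor receptor, rose by 3.33, from controls detected on 1 of 2 arrays, and the mast cell protease Mcpt1 rose at least 1.36-fold. Lcn2, a neutrophil siderophore-binding protein, rose by 3.70 and Mpo (myeloperoxidase) fell by 1.99, with 1 of 3 further probes level, within a neutrophil list that camera did not call. The adult beta-globin genes Hbb-bs and Hbb-bt rose by 3.14 and 3.13, with 1 of 5 further Hbb-bs probes level, whereas Hba-a1 (alpha-globin) was below detection in both BaP groups. The cell cycle and cholesterol synthesis lists shifted downward while limma called 0 of 25 and 0 of 14 genes (3 and 3 at an unadjusted p under 0.05, camera adjusted p = 0.00201 and 0.0155), and the adjusted p was 0.142 and 0.0594 with an estimated correlation. BaP arrays varied less than the others, and a fit to them alone called 2387 genes, which included all 829. The count was 536 without BaP IL-33 replicate 1, 539 without BaP IL-33 replicate 2 and 544 without BaP control replicate 2.

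**Figure D1:**
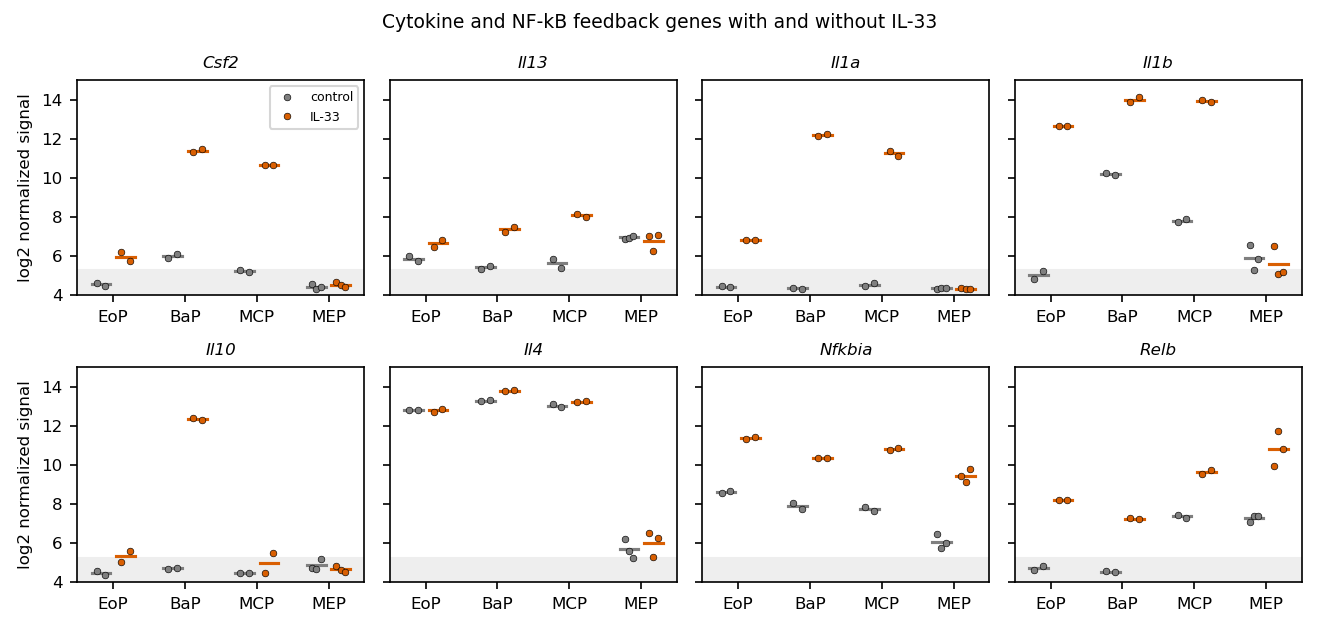
Log2 normalized signal of 8 genes (vertical axis) in the 4 progenitor populations (horizontal axis), where each point is an array, each bar a group mean, and the grey band reaches up to the highest of the arrays' lowest detected signals. Csf2 and Il1a were higher with IL-33 in EoP, BaP and MCP, Il10 was called in BaP and in no other population, and Nfkbia and Relb were higher with IL-33 in all 4 populations.

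In MCP, IL-33 raised NF-kB genes, some cytokine and chemokine genes, and the mast cell proteases Tpsab1 and Mcpt1. Csf2 rose by 5.42 ± 0.17 log2 units (SE, n = 2 and 2, adjusted p = 1.16e-10), Il1b by 6.11 ± 0.42, and Il1a at least 75.4-fold. Il6 rose by 2.66 ± 0.27, Il13 by 2.44 ± 0.25 and Il5 at least 4.11-fold, but Il5 was not called without MCP IL-33 replicate 2 (adjusted p = 0.0834). Lcn2 rose at least 67.1-fold. The number of genes that rose was 617, and 565 fell. Large rises included Gbp3 (a guanylate-binding protein, 4.60), Asb2 (a ubiquitin ligase subunit, 4.57), Ido1 (tryptophan catabolism, at least 17.7-fold) and Nox1 (an NADPH oxidase, at least 14.8-fold). Large falls were Bmp7 (-3.67, a bone morphogenetic protein), Lyl1 (a hematopoietic transcription factor, -3.64), Hrh4 (-3.28, detected on 1 of 2 arrays with IL-33), Ly6c1 (-3.12), Rapsn (-3.08), Stard9 (-3.02), Rab11fip4 (-3.01, with the 1 further probe level) and Hba-a1 (-2.91).

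Cytokine genes rose in 9 of 18 cases in MCP and fell in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 7.92e-15). Il4 was not called, at 13.03 log2 in controls and 13.25 with IL-33, and Il9 was below detection in both groups, yet passed with the authors' series matrix values and with no detection filter (adjusted p = 0.0115 and 0.0320). Chemokines rose in 8 of 17 and fell in 0 (10 and 0 adjusted over the list alone, camera adjusted p = 1.77e-12), with Cxcl2 at least 5.33-fold and Ccl1 at least 5.20-fold higher. Cxcl2 was not called by a fit to the MCP arrays alone (adjusted p = 0.0549). NF-kB genes rose in 17 of 25 and fell in 1 (17 and 1 adjusted over the list alone, camera adjusted p = 1.73e-15), including Tnfrsf9 (4.36, with 1 of 2 further probes level) and Cd40 (4.06, with 1 of 3 further probes level). Cholesterol synthesis genes rose in 5 of 14 and fell in 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.00474), with Hsd17b7 at 1.58 and the sterol demethylase Cyp51 at 1.92. Cyp51 lost its call without any 1 of the 4 MCP arrays (adjusted p from 0.0833 to 0.198), and with no background correction, a background offset of 50 or no detection filter (0.0954, 0.0756 and 0.0646).

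The unfolded protein response list had 6 of 16 genes rising and 1 falling in MCP (8 and 1 adjusted over the list alone, camera adjusted p = 0.00739), including the chaperone Calr (1.57) and Trib3 (-1.36), and its adjusted p was 0.0934 with an estimated correlation. Calr stood at an adjusted p of 0.0498 and was not called without any 1 of the 4 MCP arrays (0.155 to 0.224). Its call was also lost with no background correction, a background offset of 50, median scaling, the authors' series matrix values, no detection filter or MEP arrays normalized apart (0.0599 to 0.165). Mast cell markers rose in 5 of 15 cases and fell in 2 (5 and 2 adjusted over the list alone, camera adjusted p = 0.0230). The tryptase Tpsab1 rose by 2.46 ± 0.15 and Mcpt1 by 2.21. The list was not called with an estimated correlation, in the MCP arrays alone or with a replicate block within population (adjusted p = 0.0758, 0.119 and 0.0562). Immediate early genes rose in 5 of 16 (5 adjusted over the list alone, camera adjusted p = 0.00827), with Egr2 at 2.79 and Egr1 at 1.58 (adjusted p = 0.0934 with an estimated correlation). The innate and T lymphocyte list had 5 of 11 genes rising and 1 falling (5 and 2 adjusted over the list alone, camera adjusted p = 0.0103). It included the IL-7 receptor chain Il7r (2.83, with 1 of 3 further probes level) and the costimulator Icos (2.62), and its adjusted p was 0.0688 with an estimated correlation and 0.154 for the MCP arrays alone. The neutrophil list shifted upward with only Lcn2 of 16 called (1 adjusted over the list alone, camera adjusted p = 0.0217). The list was not called with an estimated correlation, in the MCP arrays alone or without MCP IL-33 replicate 2 (adjusted p = 0.418, 0.225 and 0.8003). Its median of 0.30 turned to -0.049 without that array. Hbb-bt rose by 1.96 while Hba-a1 fell. Of megakaryocyte genes Nfe2 fell by 1.88 and Gp1bb at least 2.84-fold, and of monocyte genes Cx3cr1 fell by 2.34 and C1qb at least 3.44-fold, within lists that camera did not call. The eosinophil gene Prg2, chosen after its values were seen, ran from 4.37, below detection, to 12.5 log2 between the MCP arrays with IL-33 and from 9.03 to 11.41 between their controls. The count was 746 without MCP IL-33 replicate 1 and 693 without MCP IL-33 replicate 2.

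In MEP, IL-33 raised NF-kB feedback genes and a small set of other genes, and limma called 0 of the 18 cytokine genes (2 at an unadjusted p under 0.05). Dhh, which encodes desert hedgehog, rose at least 48.6-fold (n = 3 and 3, adjusted p = 1.97e-10). Tph1 rose by 5.91 ± 0.25 log2 units, and Ano9 (an anoctamin membrane protein) rose at least 42.2-fold. Whrn (at least 19.2-fold), Wnt10b (a Wnt ligand, at least 14.9-fold), Slc2a6 (a glucose transporter family member, at least 14.6-fold), App (amyloid precursor protein, 4.29) and Mylk (myosin light chain kinase, at least 11.7-fold) followed. The fit to all arrays called 242 genes, of which 174 rose and 68 fell (172 and 39 with median scaling). A fit to the MEP arrays alone called 48, of which 45 rose and 3 fell, and all 48 were among the 242. All 8 of these rises were called in both fits. Of 8 large falls, only Pparg (a lipid-sensing nuclear receptor, -1.90) and Nkg7 (at least 2.70-fold) were called by the fit to MEP alone. Lmnb2 (-2.78), Tac2 (-2.04, detected on 1 of 3 arrays with IL-33), Ddc (-1.96, detected on 1 of 3), Spon2 (-1.90), Il10ra (at least 2.48-fold) and Rnd2 (at least 2.37-fold) were not. The 1 further probe of Lmnb2 and of Spon2 and both further probes of Ddc stayed level, and Ddc was also lost with the authors' series matrix values (adjusted p = 0.0550).

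NF-kB genes rose in 11 of 25 cases in MEP and fell in 0 (12 and 0 adjusted over the list alone, camera adjusted p = 1.01e-19). Relb rose by 3.53 and Nfkbie, an NF-kB inhibitor, by 3.51, and 6 of the 25 rose in the fit to MEP arrays alone. The list's median of 0.73 ran from 0.36 to 1.05 over the other settings. Of 19 interferon response genes 3 rose (3 rising and 3 falling adjusted over the list alone), including the transcription factor Irf1 (3.21, with 2 of 3 further probes level) and Gbp2 (2.26, detected on 2 of 3 control arrays), and camera did not call the list. Gbp2 was not called by the MEP fit alone. Csf2, Il5, Il6 and Il9 were below detection in both MEP groups, and Il4 (0.34) and Il13 (-0.18) were not called. Of 25 erythroid genes limma called 0 (1 at an unadjusted p under 0.05). Hbb-bs, Hba-a1 and Slc4a1 stood at 14.31, 14.20 and 14.20 in MEP controls, whose highest gene was at 14.41, so a rise of these could hardly be measured. Megakaryocyte and platelet genes shifted downward with 1 of 17 falling (4 adjusted over the list alone, camera adjusted p = 0.0197), and the adjusted p was 0.084 with an estimated correlation. That list was called in 11 of 17 other settings. It was lost with no background correction, with the authors' series matrix values and with no detection filter (adjusted p = 0.0514, 0.147 and 0.169). It was also lost without MEP IL-33 replicate 1, MEP IL-33 replicate 2 or MEP control replicate 3 (0.450, 0.0897 and 0.143). MEP arrays varied more than the shared variance assumed, and the count was 628 without MEP IL-33 replicate 2, with 347 rising and 281 falling.

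**Figure D2:**
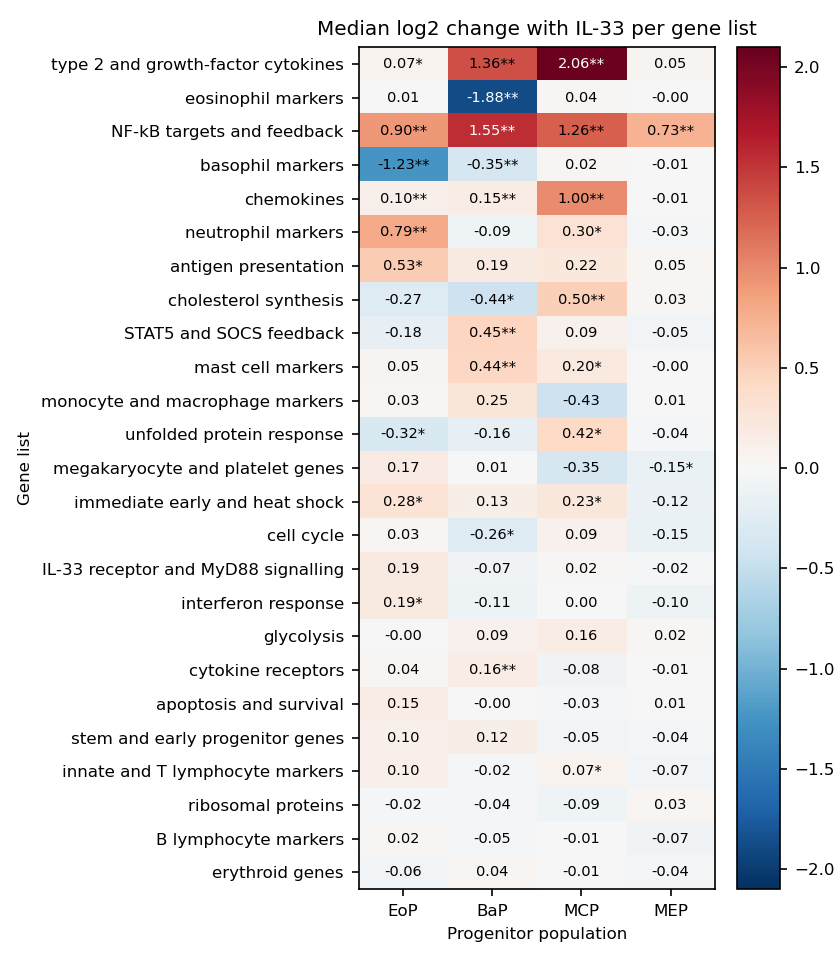
Median fitted log2 change with IL-33 (colour and printed value) of 25 gene lists (vertical axis) in 4 populations (horizontal axis), where 1 asterisk marks a list called by camera at a preset correlation and a pair of asterisks one also called with an estimated correlation. NF-kB targets were called in all 4 populations, from 0.73 in MEP to 1.55 in BaP (0.34 and 1.23 with genes below detection at their bound), and basophil markers had their lowest median in EoP, at -1.23.

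Of the other fixed lists, camera called none in any of the 4 populations for IL-33 receptor and MyD88 signalling, apoptosis and survival, ribosomal proteins, glycolysis, monocyte and macrophage markers, B lymphocyte markers, erythroid genes, or stem and early progenitor genes. In each of these except glycolysis limma called some members in at least 1 population. Monocyte markers in EoP, BaP and MCP and erythroid genes in BaP and MCP had at least 3 called members. The test fry, which asks whether the genes of a list move on balance in one direction without comparing them with other genes, passed stem and early progenitor genes in EoP, BaP and MCP (adjusted p = 0.00982, 0.00161 and 0.0247). It also passed erythroid genes and monocyte markers in BaP (0.0102 and 0.0264). With genes below detection held at their bound, the median was 0 for the called lists of chemokines in EoP, mast cell markers in BaP, and neutrophil and innate and T lymphocyte markers in MCP. With an estimated correlation 4 of the 9 lists called by camera held in EoP, 8 of 10 in BaP, 4 of 9 in MCP and 1 of 2 in MEP. Il1rap, the co-receptor chain for IL-33, was not called in any population, with changes from 0.03 in BaP to 0.68 in EoP.

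The IL-33 responses overlapped between populations but differed in many genes. Over all genes the log2 changes correlated at 0.326 for EoP and BaP, 0.334 for BaP and MCP, and 0.155 for EoP and MCP. With MEP the correlations were 0.071 to 0.136. Counts for independent lists are only a rough guide, because the comparisons share 1 variance per gene. EoP and BaP shared 163 rising genes against 17.6 for independent lists of those sizes, EoP and MCP 114 against 20.6, and BaP and MCP 171 against 26.1. MEP shared 36 with EoP against 5.80, 48 with BaP against 7.37, and 50 with MCP against 8.63. Shared falling genes numbered 43 for EoP and BaP against 5.19, 32 for EoP and MCP against 9.71, and 78 for BaP and MCP against 13.7. With MEP they were few, at 3 for EoP against 1.17, 6 for BaP against 1.65, and 8 for MCP against 3.09. There were 22 genes that rose in all 4 populations, against 0.0122 for independent lists, and 0 that fell in all 4. They included Relb, Nfkbiz, Tnfrsf9, Gbp3 and Tpbg, and also Nfkbia (NF-kB inhibitor alpha) and Tnfaip3 (the feedback regulator A20), which were chosen after their values were seen. Nfkbia rose by 2.75 in EoP, 2.43 in BaP, 3.05 in MCP and 3.36 in MEP. Of the 22 genes, 11 were also called in the fit to MEP arrays alone, Nfkbia among them and Tnfaip3 not (adjusted p = 0.217), and 8 were called in each population fitted alone. Tnfaip3 in MEP was also lost with a background offset of 50 (adjusted p = 0.0583).

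Tests of the difference itself called 606 genes between EoP and BaP, 851 between EoP and MCP, 526 between EoP and MEP, 759 between BaP and MCP, 626 between BaP and MEP, and 749 between MCP and MEP. The count for EoP and BaP was 392 without BaP IL-33 replicate 1 and 400 without BaP control replicate 2. For BaP and MCP it was 469, 476 and 457 without BaP IL-33 replicate 1, BaP IL-33 replicate 2 and BaP control replicate 2. For BaP and MEP it was 411 without BaP control replicate 2, and for EoP and MEP 808 without MEP IL-33 replicate 2. Fits to the arrays of each pair alone gave 1119 for EoP and BaP, 1608 for BaP and MCP, 299 for EoP and MEP and 423 for MCP and MEP. Il10 rose in BaP and was not called in EoP, MCP or MEP (in MCP it was without MCP IL-33 replicate 1, adjusted p = 0.0365), and its effect differed between BaP and each of these (adjusted p = 1.86e-07, 9.96e-08 and 8.28e-09). Tph1 rose in BaP and was not called in MCP, where it was already at 14.02 in controls (adjusted p of the difference = 3.49e-08). The highest gene in MCP controls stood at 14.40, so Tph1 had little room to rise there, which limits that difference. Ear6 fell in BaP and stood at 14.28 and 14.31 in EoP, also near the top of the scale. It rose by 2.63 in MCP, a call lost in the MCP arrays alone (adjusted p = 0.186). The call was also lost without MCP control replicate 1, MCP control replicate 2 or MCP IL-33 replicate 2, where the rise was 2.81, 2.45 and 1.04. The effect differed, with adjusted p values of the difference of 3.95e-05 between BaP and MCP and 9.92e-04 between EoP and BaP. Edn1, which encodes endothelin 1, rose by at least 4.83 log2 units in BaP. In EoP, where it was detected on 1 of 2 arrays of each group, its change of -1.10 was not called, except without EoP control replicate 1 (-2.72, adjusted p = 0.00886).

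Between EoP and MCP 65 genes moved in opposite directions, among them the 3 named genes of that pair. Cd226, an activating receptor, fell by 2.24 in EoP and rose by at least 3.55 log2 units in MCP. Akr1c18 fell in EoP and rose by 1.38 in MCP, and Mmp2 rose in EoP and fell by at least 1.75 log2 units in MCP. The fall of Cd226 and the rise of Akr1c18 were not called in the arrays of their population alone (adjusted p = 0.107 and 0.152). The rise of Akr1c18 was also not called without MCP IL-33 replicate 1 or MCP control replicate 2, where it was 1.17 and 0.67 log2 units. The difference between EoP and MCP was called for all 3 genes in every setting tried. Il1b rose in EoP and was not called in MEP (-0.30). Il1a rose in BaP and MCP and was below detection in both MEP groups, as was Lcn2 in MEP. Dhh rose in MEP and was below detection in both groups of EoP, BaP and MCP, and Ano9 was below detection in both EoP groups. Differences were called by camera for the cytokine list between EoP and BaP (adjusted p = 4.31e-09) and between EoP and MCP (adjusted p = 3.01e-08), with the smaller shift in EoP. Between BaP and MCP camera did not call the cytokine list. Basophil markers differed between EoP and BaP (adjusted p = 1.71e-05) and between EoP and MCP (adjusted p = 9.03e-06). Eosinophil markers differed between EoP and BaP, but their adjusted p was 0.109 with an estimated correlation.

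**Figure D3:**
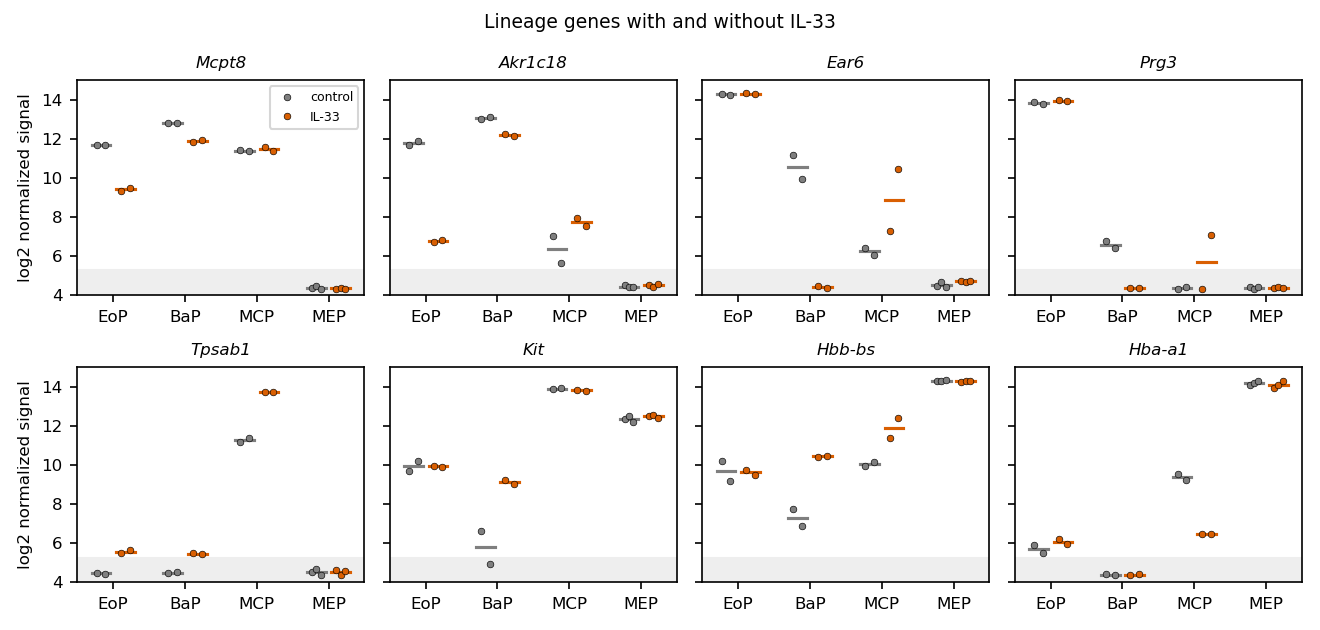
Log2 normalized signal of 8 lineage genes (vertical axis) in the 4 populations (horizontal axis), where each point is an array, each bar a group mean, and the grey band reaches up to the highest of the arrays' lowest detected signals. Mcpt8 and Akr1c18 were lower with IL-33 in EoP, Ear6 and Prg3 in BaP, and Hbb-bs was higher with IL-33 in BaP and MCP without a rise of Hba-a1.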

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

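The tests of the beta-globin rise were chosen after that result was seen, whereas the other tests were set before the result they measure was seen.

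The IL-33 effect itself differed between populations by the limma test of the difference. The number of such genes was 606 for EoP and BaP, 851 for EoP and MCP, 526 for EoP and MEP, 759 for BaP and MCP, 626 for BaP and MEP, and 749 for MCP and MEP. The genes with the largest fitted differences follow, as log2 differences that are no bounds where a gene was below detection in one group. Tph1 in MCP and Ear6 in EoP stood near the top of the scale, which limits their differences. For EoP minus BaP, Il10 differed by -6.80, Ear6 by 6.18 and Edn1 by -6.04. For EoP minus MCP, Cd226 differed by -6.42, Akr1c18 by -6.396 and Mmp2 by 6.26. The effect in EoP minus that in MEP was 7.93 for Il1b, -6.48 for Dhh and -5.99 for Ano9. BaP minus MCP gave -8.78 for Ear6, 8.50 for Tph1 and 7.13 for Il10. BaP minus MEP gave 7.88 for Il1a, 7.82 for Il10 and -6.41 for Dhh. In MCP minus MEP, Dhh was at -6.86, Lcn2 at 6.79 and Il1a at 6.73.

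Probes without a gene name entered no comparison of genes, yet some of the 4407 kept ones were called with IL-33 when tested on their own. These were 121 in EoP (65 higher and 56 lower), 172 in BaP (98 and 74), 282 in MCP (128 and 154) and 45 in MEP (35 and 10). They made up 2.75%, 3.90%, 6.399% and 1.02% of the unnamed probes, against 4.28%, 5.73%, 8.41% and 1.61% of the named ones.

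Basophil markers fell in EoP with IL-33, at a list median of -1.23, and a lower share of basophil-lineage cells would lower other genes that are high in BaP as well. Over 91 genes at least 3 log2 units higher in BaP than in EoP controls, detected in EoP controls and not called with IL-33 in BaP, the median change in EoP was 0.018 (bootstrap interval -0.14 to 0.12, quartiles -0.51 and 0.37), with 15 of them called as falling and 6 as rising. That median shows no fall of the set as a whole, but it cannot exclude a lower share of basophil-lineage cells. Genes that EoP express themselves would show little of such a loss, and the interval resamples genes, which are not independent. The falls also outnumber the rises, so a part played by a lower share stays open. Between-array normalization is set against a list median that stayed between -1.22 and -0.92 over the other normalizations, with a largest camera adjusted p of 6.25e-13. A change of these genes within EoP stays open and was not tested.

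Eosinophil markers fell in BaP with IL-33, at a list median of -1.88. Over 115 genes at least 3 log2 units higher in EoP than in BaP controls, chosen in the same way, the median change in BaP was 0.17 (bootstrap interval 0.06 to 0.24, quartiles -0.34 and 0.73), with 12 called as falling and 15 as rising. That median shows no fall of the set as a whole, but it cannot exclude a lower share of eosinophil-lineage cells. Genes that BaP express themselves would show little of such a loss, and the interval resamples genes, which are not independent. The markers Epx, Prg3, Ear10, Ear6 and Alox15 were detected on 2 of 2 BaP control arrays and on 0 of 2 with IL-33, while Il5ra went from 0 to 2. A part played by a lower share stays open. Over the other normalizations the list median lay between -2.28 and -1.06, with a largest camera adjusted p of 9.78e-07, so normalization does not account for the fall. A change within BaP stays open and was not tested.

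Beta-globin rose with IL-33 in BaP (Hbb-bs by 3.14, Hbb-bt by 3.13) and in MCP (Hbb-bt by 1.96). Earlier comparisons took an erythroid share from Hbb-bs, and the second was chosen after the first result was seen. They measured how far other abundant MEP transcripts lay, with IL-33, from the log2 level that this share gives. Over 34 transcripts the median was -0.50 in BaP and -2.13 in MCP. Over those well below that level in controls it was -5.05 in BaP (11 transcripts) and -4.43 in MCP (20 transcripts). No conclusion is drawn from these, because Hbb-bs was at 14.31 in MEP controls, whose highest gene was at 14.41. Over the 4 beta-globin probes that rose and lay at least 1 log2 unit below that top in MEP, the gain with IL-33 was 0.685% or more of their MEP signal in BaP and 2.37% or more in MCP. Other transcripts as abundant in MEP and below detection in controls gained a median of 0.00575% in BaP (9 transcripts, quartiles -0.00108% and 0.0120%, highest 0.607%) and 0.0294% in MCP (6 transcripts, highest 0.247%), which argues against erythroid cells like the MEP cultures as the source of the rise, and Hba-a1 was below detection in both BaP groups and fell in MCP from 9.40 to 6.48. A fault of a single probe is set against 9 of 10 adult beta-globin probes that rose by at least 1 log2 unit in BaP. Transcription of beta-globin in BaP and MCP themselves and cells of another erythroid profile stay open and were not tested.

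For the IL-33 effect in MEP, 3 of the 10 splits of the 6 arrays into 3 and 3, the real one included, gave as many genes as the real split. The real split gave 242 and the highest other 2102, for MEP control replicate 1, MEP IL-33 replicate 1 and MEP IL-33 replicate 3 against the rest. With 10 splits the share cannot go under 0.1, so the splits are too few for a share under 0.05. A further split gave 701, for MEP control replicates 1 and 2 with MEP IL-33 replicate 1 against the rest. A split that calls many more genes than the real one points to a structure of the MEP samples other than IL-33.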

How the results depend on the processing

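All alternatives were planned except the MEP arrays normalized apart and a crossed pairing of the BaP arrays, which were chosen after seeing the data. Of 2964 checks of 190 single-gene effects, 2870 kept the side of the threshold, 83 lost the call and 11 gained it. Among effects called in either fit 0 reversed, while sign changes of effects called in neither were not counted. All 369 checks of the 18 named differences kept direction and call. Fits to only the arrays compared gave 349 genes for EoP, 2387 for BaP and 48 for MEP, and 1119 differing between EoP and BaP, 299 between EoP and MEP, 1608 between BaP and MCP and 423 between MCP and MEP. By construction these fits used fewer arrays and each population's own spread. Genes highest in controls numbered 2245 in BaP and 1856 in MEP with median scaling, for which the cause was not tested, and 2342 and 4683 with every probe on its own, where more probes than genes were counted. Lists called in MEP went from 2 to 1 without background correction, with series matrix values and without a detection filter, for which the cause was not tested. The estimated correlation left 4 lists in EoP, 4 in MCP and 1 in MEP. Without 1 array in turn, where a lone array was assumed to vary like the other groups, the IL-33 counts ran from 429 to 497 in EoP, 536 to 558 in BaP, 693 to 820 in MCP and 184 to 628 in MEP. Differing genes ran from 392 to 521 for EoP and BaP, 619 to 743 for EoP and MCP, 405 to 808 for EoP and MEP, 457 to 634 for BaP and MCP, 411 to 775 for BaP and MEP, and 512 to 1077 for MCP and MEP. Lists in MEP ran from 1 to 2. Fewer arrays lower the counts by construction, but they rose to 628, 808, 775 and 1077, each without MEP IL-33 replicate 2. Among the MEP arrays that one had the largest SD of genes around its group mean, at 0.443. The cause of the rise was not tested. With a replicate block within populations the counts were 583, 813, 1261 and 267 for EoP, BaP, MCP and MEP, and with MEP arrays normalized apart 699, 898, 1262 and 213. The crossed BaP pairing gave 762. Slide was not run, since none is given, and series matrix values were not used for genes highest in controls. Low signal over background limits genes near detection. Changes of genes undetected on all arrays of a group are given as bounds, but fitted values stand for genes detected on some arrays and for differences between populations.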

Other observations

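The values here come from genes and arrays chosen after their values were seen. In BaP, IL-33 also raised a pair of genes outside the named set. Cd34, a stem and progenitor surface protein, rose by 2.92 ± 0.26 log2 units, with detection on 1 of 2 control arrays. Gata3, a transcription factor of T and innate lymphocytes, rose at least 6.43-fold from controls below detection, beside the rise of Kit by 3.33. Across genes, which are not independent replicates, BaP and MCP arrays correlated at 0.869 to 0.885 in controls and at 0.910 to 0.916 with IL-33, a difference that was not tested.

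Prg2, an eosinophil granule protein gene, was at 13.04 and 13.05 log2 in BaP controls and at 9.79 and 10.17 in BaP with IL-33, and was called there by the fit to BaP arrays alone (adjusted p = 5.73e-07) but not by the fit to all arrays (adjusted p = 0.473). In MCP it was at 9.03 and 11.41 in controls and at 4.37, below detection, and 12.5 with IL-33. Without the latter array it was called as lower in MCP (adjusted p = 1.16e-04), and no size is given because the array that remained was below detection. MCP IL-33 replicate 2 was also above MCP IL-33 replicate 1 for Epx (5.76 against 4.51), Prg3 (7.10 against 4.33), Ear6 (10.46 against 7.29) and Mpo (6.13 against 4.54). Epx, Prg3 and Mpo were below detection on MCP IL-33 replicate 1.

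Xist, the X-inactivation transcript, was at 5.43 to 7.18 log2 in the 6 MEP arrays and at 10.5 to 12.2 in the other 12. The Y-linked genes Eif2s3y and Uty were at 4.75 to 5.47 and 5.17 to 6.23 over all 18 arrays. Uty was detected on every array. Eif2s3y was detected on 2 of 3 MEP control arrays and 3 of 3 with IL-33. In EoP it was detected on 2 of 2 control arrays and 0 of 2 with IL-33. In MCP these counts were 1 and 0, and in BaP 1 and 1. The cause of the Xist difference was not tested, and that difference is part of every comparison with MEP.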
